A study of Mus musculus with 64 samples.

How the data were processed

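RNA from the hippocampus of 64 mouse samples was measured by bulk RNA sequencing. The samples cover 8 inbred strains and both sexes with 4 samples in each of the 16 groups of strain and sex, as the labels give them. The strains are the 8 founders of the Collaborative Cross and Diversity Outbred mouse populations. Strain names are written here with a slash where the labels use another character. Per the labels' protocols, total RNA was isolated with a TRIzol Plus kit that included DNase digestion on the column, and libraries were made with an Illumina TruSeq kit. Neither the type of TruSeq kit nor the use of strand in the counting is stated, so overlapping antisense genes cannot be separated.

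The authors deposited 1 table of raw counts per gene for all samples, with whole numbers and no normalization. The genome build was GRCm39, per the submitters' processing notes, and the name of the deposited table gives Ensembl release 105. The aligner and the counting tool were not given in the sources used here. Whether reads were aligned to the C57BL/6J reference alone or to genomes of each strain was not given either, and reads of strains far from the reference can be lost or moved to a related gene in the former case. Columns were matched to samples by name. For 50 columns the name equalled the first 3 parts of a sample title, and for 14 the last of these parts held a single digit more in the title than in the column. No per-sample column was left unused. Samples of a group were numbered 1 to 4 in deposition order, which only names them. The CAST/EiJ females carry title numbers 639 to 643, and the other samples carry 311 to 462. Sex and number block are confounded in that strain. In the other strains the numbers also run by strain, with all females before all males. Strain and sex therefore follow the order of title numbers throughout, and what this order reflects is not stated.

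Gene symbols, gene types and chromosomes were looked up by Ensembl identifier in GENCODE M21, an annotation of the earlier build GRCm38. No coordinates are reported from it, and its gene positions served only to find the genes nearest to Kbtbd7. Of the 32227 identifiers, 32146 (99.7%) were matched, and the 81 others held 0.0382% of all counts. Reads shared between near-identical genes (paralogs, pseudogenes, clustered families) could have been split differently by the authors' counting in each strain, and such genes are reported as uncertain.

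Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 16 groups (minimum count 10, minimum total 15), which left 17382 genes (53.9%), and libraries were scaled by TMM. A single model with 16 group means was fitted to all 64 libraries with estimateDisp and a robust quasi-likelihood fit, leaving 48 residual degrees of freedom. The tests were an F test over the 8 strains with 7 degrees of freedom, each strain against the mean of the other 7, all 28 pairs of strains, female against male over all strains, female against male within each strain, and the interaction of strain and sex. P-values were adjusted over the genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. Comparisons between strains also required an absolute log2 fold change, or a range of strain means, of at least 1. The sex and interaction tests had no fold minimum. Levels are counts scaled to library size (CPM, with TMM factors), given as mean ± SD over samples, and log2 fold changes are those of the edgeR fit.

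A total of 37 gene lists was written before the data were examined, as were the design, the rule for named genes and all but a pair of the alternatives. The lists were X genes that escape inactivation, Y genes, genes of textbook strain variants, markers of CA1, CA2 and CA3 pyramidal neurons, dentate granule neurons, interneurons, and neurogenesis. Others were markers of astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, meningeal fibroblasts, choroid plexus, ependymal cells, thalamus and habenula, striatum, neocortex and blood. They further held immediate early genes, glucocorticoid response genes, circadian clock genes, interferon-stimulated genes, MHC class I and class II genes and complement genes. The rest were glutamate receptor genes, GABA-A receptor genes, opioid, dopamine and endocannabinoid genes, glutathione and detoxification genes, steroid hormone genes, symbols starting with Zfp, cytosolic ribosomal protein genes, nuclear genes of oxidative phosphorylation and the protein genes of the mitochondrial genome. Each list with at least 4 tested members was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, for 9 contrasts, and adjusted over lists and contrasts. Adjustment over the list alone was also run for the members of each list.

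Genes named in the text were chosen by a rule among protein-coding genes with an official symbol. Named were the 24 genes with the widest range of strain means among those with a mean of at least 8 CPM, and for each strain up to 6 rises and 6 falls with at least 4 CPM in either side and all 8 samples outside the range of the 56 others. For sex, the rule took the 15 highest and 15 lowest log2 fold changes over all strains and up to 6 each way within a strain. It further took up to 20 genes with the smallest interaction p, and members of the fixed lists. Genes named outside this rule are said to have been chosen after their values were seen.

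Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in place of TMM, no count filter, a mean of at least 50 counts, no fold minimum, a log2 minimum of 2, an additive model of strain and sex, and the mean of the choroid plexus markers as a covariate. Further ones were autosomal genes alone, no CAST/EiJ samples, only the 8 samples of a strain, each library left out in turn, and camera with an estimated correlation. DESeq2 was run on all genes with a count and not only on those kept by filterByExpr. The choroid plexus is a secretory tissue beside the hippocampus that can be carried over in dissection. A pair of alternatives was added after seeing the data. The first left out the libraries that stood more than 5 median absolute deviations from the rest on the second component of the within-group residuals, and the second left out NOD/ShiLtJ females 1 and 2.

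The procedures were tested on simulated data drawn from the real means and library sizes, with 200 changed genes among 17382. For C57BL/6J against the other strains, 92% of genes changed by a log2 of 1.2 and 99% of those changed by 2 were recovered. For sex over all strains, 79% were recovered at 0.25 and 85% at 0.5, and for sex within NOD/ShiLtJ 56% at 0.5 and 77% at 1. The interaction test recovered 33% at 0.5 and 70% at 1. The labels do not state that samples of a group came from separate animals, and p-values measure only the spread between these samples, which may be technical. All 96 pairs of samples within a group were compared, and their counts differed by more than sampling noise in every pair (chi-square over its degrees of freedom 2.86 to 57.7). No pair therefore looked like copies of the same library, but repeat libraries of the same animal would differ in this way as well, so this does not show separate animals. Depth limits precision mainly for genes of a few CPM, with total counts of 16607602 to 27759221 per library. Some results for single genes are not reported here.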

Results

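Hippocampal gene expression was compared among 8 inbred mouse strains in both sexes, with 64 libraries in 16 groups of 4. The strains were C57BL/6J (the reference strain), 129S1/SvImJ, NOD/ShiLtJ (a model of autoimmune diabetes), A/J, NZO/HlLtJ (a model of obesity and diabetes) and the wild-derived CAST/EiJ, PWK/PhJ and WSB/EiJ. Total counts per library ran from 16607602 to 27759221 with a median of 22176356.5, and 19596 to 20973 genes had a count. Of the 17382 genes tested, 15455 were protein coding, 16762 autosomal, 576 X-linked and 10 Y-linked. Levels below are counts scaled to library size (CPM) as mean ± SD, with n = 8 for a strain and n = 56 for the 7 other strains unless stated. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

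Strain was the main axis of variation in these hippocampi. The first principal component held 21.7% of the variance, and strain explained 99.7% of it. The second held 13.3%, of which strain explained 97.9%. For the median gene, strain accounted for 51.1% of the variance against 11.1% under chance. Sex accounted for 0.274% against 1.59%, and the interaction of strain and sex for 6.53% against 11.1%. These chance shares are means that hold only where no term has an effect. As strain left a residual of 40.1% over 48 degrees of freedom, they are too high a yardstick for sex and the interaction. The shares of sex and the interaction can therefore not be read as below chance. The library most correlated with each library came from the same strain for 63 of the 64, the exception being 129S1/SvImJ female 1, nearest to A/J male 2. A total of 4569 genes (26.3%) differed among strains with a range of strain means of at least 1 on the log2 scale (edgeR F test), and 15513 did so without that minimum.

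**Figure D1:**
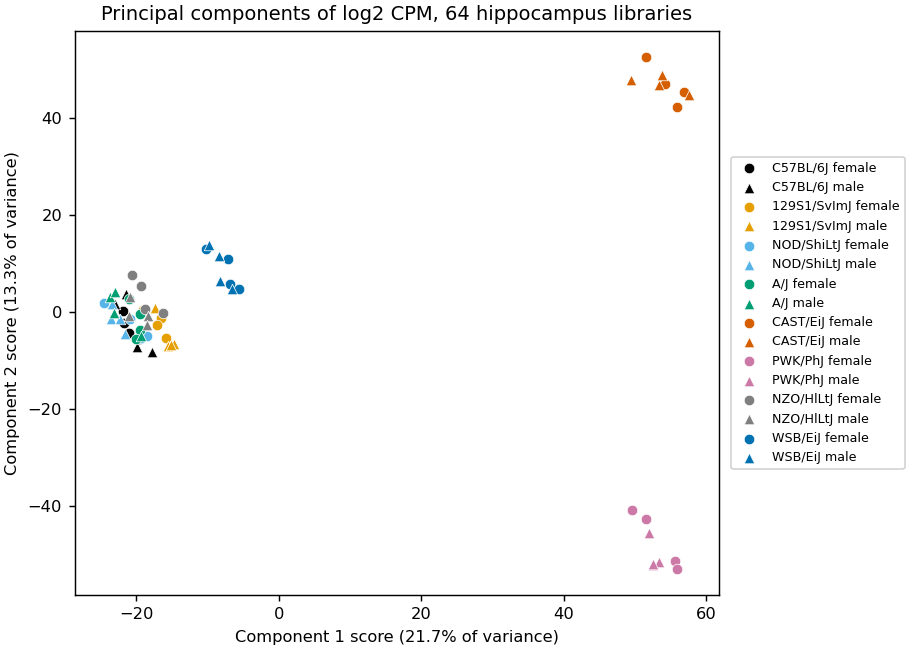
First against second principal component of log2 CPM over the 17382 tested genes (axes in component score units, with the percent of variance), where each point is 1 of the 64 libraries, coloured by strain and marked by sex. The first component holds 21.7% and the second 13.3% of the variance, and libraries lie together by strain and not by sex.

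A total of 24 genes was named for wide differences among strains. Thbs4, an extracellular matrix thrombospondin, was at 31.8 ± 4.70 CPM in A/J and 23 ± 2.23 in CAST/EiJ against 2.05 ± 0.474 in PWK/PhJ. Fcrls, a microglial Fc receptor-like gene, ranged from 29.9 ± 2.97 in CAST/EiJ and 25.9 ± 3.64 in C57BL/6J to 2.0 ± 0.349 in PWK/PhJ. A2ml1, a protease inhibitor of the macroglobulin family, was at 14.2 ± 1.64 in WSB/EiJ and lower in CAST/EiJ (1.70 ± 0.241) and PWK/PhJ (0.967 ± 0.315). Cyp4f15, a fatty acid hydroxylase, was at 0.966 ± 0.342 in PWK/PhJ and 6.88 to 14.3 in the other strains. Ahcy, which hydrolyses S-adenosylhomocysteine, was at 35.1 ± 1.43 in C57BL/6J, 34.6 ± 3.19 in A/J, 26.2 ± 2.27 in CAST/EiJ and 35.5 ± 1.97 in PWK/PhJ. It was at 2.17 to 3.04 in the other strains. Ahcy has processed copies that may share its reads and is uncertain, as are AK157302, Hmga1b, Tpm3-rs7, Amd2, Eno1b, Rpl9 and Cwc22 among the same 24 genes. Crym (range 5.35) and Dsp (5.13) are described with their strains below. The log2 ranges of the 24 ran from 3.79 (A2ml1) to 8.80 (AK157302).

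Each strain was next set against the mean of the other 7. A call does not make a gene particular to the strain, since a large change in a single strain shifts the mean of the others. Each strain enters that mean, so the 8 comparisons are not independent. In A/J, 13 of the 377 higher and 14 of the 246 lower genes had all 8 libraries outside all others. This held for 16 of 478 and 15 of 202 in NOD/ShiLtJ, and for 205 of 699 and 144 of 908 in CAST/EiJ. Counts of called genes were largest in CAST/EiJ (1607 genes) and PWK/PhJ (1625), followed by WSB/EiJ (860), NOD/ShiLtJ (680), C57BL/6J (670), NZO/HlLtJ (634), 129S1/SvImJ (632) and A/J (623). Genes lower than in the other strains were 56.5% of those called in CAST/EiJ and 59.9% in PWK/PhJ, against 26.8% in NZO/HlLtJ and 29.7% in NOD/ShiLtJ. This balance depended on the settings. Without a count filter it turned, with 1626 higher and 1248 lower in CAST/EiJ and 1586 and 1328 in PWK/PhJ, and without a fold minimum it was near even (4923 and 4950, and 5029 and 5001). Genes named for a strain were chosen to have its 8 libraries above or below all 56 others, so this holds by selection and is no further evidence for them. The calls for the 94 single genes of a strain held with DESeq2, its size factors, no count filter, the choroid plexus covariate, the additive model, without the libraries that stand apart and with each of the strain's 8 libraries left out. With a mean of at least 50 counts 80 of them were tested and held. The log2 minimum of 2 was not applied to single genes and by construction ends the calls below it, such as that for Lpl (-1.11). The counts themselves moved by more than 1.5 times with the fold minimum and the count filter. Without a fold minimum they ran from 5608 in 129S1/SvImJ to 10030 in PWK/PhJ. Between pairs of strains, the median count over the 28 pairs was 1096.5, from 661 between NOD/ShiLtJ and A/J to 2025 between PWK/PhJ and NZO/HlLtJ. The pairs without CAST/EiJ and PWK/PhJ had 661 to 1101, and these wild-derived strains differed from each other by 2000 genes.

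**Figure D2:**
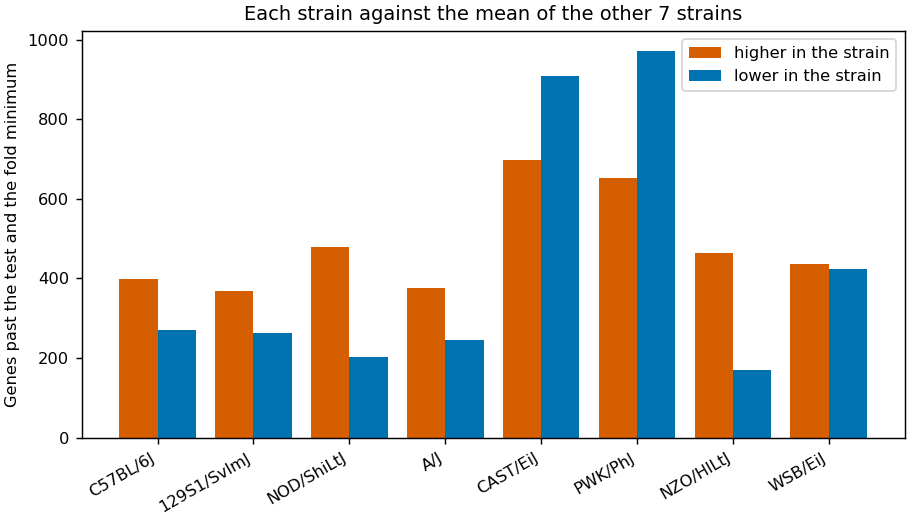
Number of genes (vertical axis) higher and lower in each strain than the mean of the other 7 at an adjusted p under 0.05 and a log2 fold change of at least 1, with 8 libraries in each strain. In CAST/EiJ 699 genes were higher and 908 lower, and in PWK/PhJ 652 and 973, whereas in NOD/ShiLtJ 478 were higher and 202 lower. Without the count filter the balance turned in CAST/EiJ and PWK/PhJ.

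In C57BL/6J, Gabra2, an alpha subunit of the GABA-A receptor, was at 82.8 ± 5.30 CPM against 313 ± 59.0 in the other strains, a log2 fold change of -1.90 (SE 0.0385, edgeR adjusted p = 1.69e-43). Its level was 448 ± 22.6 in PWK/PhJ and had means of 279 to 304 in the remaining 6 strains. Wdfy1, an endosomal protein of innate immune signalling, was at 12 ± 1.0 against 50.4 ± 3.71 (log2 -2.06, edgeR adjusted p = 3.61e-44). Pla2g4e, a phospholipase, was at 4.39 ± 0.738 against 20.6 ± 7.26. Lpl (lipoprotein lipase) fell by 1.11 and Col11a1, a fibrillar collagen, by 1.70 on the log2 scale. Pttg1, the securin of the cell cycle, rose from 0.529 ± 0.357 in the other strains to 22.1 ± 1.93 (log2 5.58, SE 0.0768, edgeR adjusted p = 6.07e-52). Myoc, a secreted glycoprotein, rose from 2.67 ± 3.53 to 17.5 ± 3.35. Of the 399 genes higher in this strain, 31 had all 8 libraries above all others, and of the 271 lower, 10 had all below. Srp54b and Entpd4b were also among the named rises and are uncertain because of near-identical copies. As sets, interferon-stimulated genes were higher (median log2 0.60, camera adjusted p = 2.32e-05, adjusted p = 0.598 with an estimated correlation). Higher too were oligodendrocyte markers (camera 4.71e-05, adjusted p = 0.813 with an estimated correlation) and MHC class I genes (0.000314, adjusted p = 0.636 with an estimated correlation). C57BL/6J male 4 stood apart from its group and lay 0.52 above the other 3 males in interferon-stimulated genes, 0.28 in MHC class I genes and 0.27 in oligodendrocyte markers on the log2 scale.

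**Figure D3:**
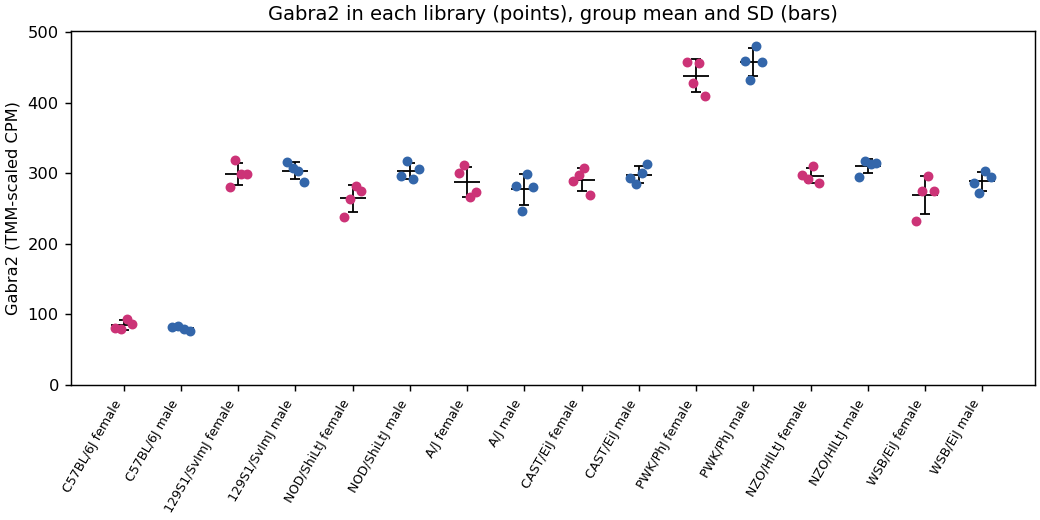
Gabra2 level in CPM (vertical axis) in each library of the 16 groups of strain and sex, with 4 points per group. All 8 C57BL/6J libraries (mean 82.8 CPM) lie below all libraries of the other strains, and PWK/PhJ has the highest mean (448 CPM).

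In 129S1/SvImJ, Gdpd3, a phospholipase D of the glycerophosphodiesterase family, was at 10.6 ± 1.57 CPM against 0.289 ± 0.145 (log2 5.25, edgeR adjusted p = 1.16e-40). Serpina3n, an acute-phase protease inhibitor made by astrocytes, was at 284 ± 17.1 against 94.7 ± 51.9 (log2 1.79, edgeR adjusted p = 8.78e-46), while in NZO/HlLtJ it was at its lowest. Fxyd2, a regulatory subunit of the sodium pump, rose by 2.28 and Xaf1, an interferon-inducible regulator of apoptosis, by 2.03 on the log2 scale. Mcm6, a subunit of the replicative helicase, was at 5.15 ± 0.770 against 15.1 ± 2.96 (log2 -1.53). Mpeg1, a pore-forming protein of macrophages and microglia, was at 6.73 ± 0.581 against 21.2 ± 8.08 (log2 -1.54). Spink8, a marker of CA1 pyramidal neurons, fell by 1.72 on the log2 scale, to 7.24 ± 1.68. Entpd4b (0.383 ± 0.246 against 34.9 ± 7.94) and Pcdhb8 belong to families with near-identical copies and are uncertain. Microglia markers were lower as a set (median log2 -0.31, 10 of 12 members lower at any fold, camera adjusted p = 4.24e-07, adjusted p = 0.343 with an estimated correlation). Lower too were complement genes (camera 4.22e-05, adjusted p = 0.155 with an estimated correlation) and astrocyte markers (0.000952, adjusted p = 0.343 with an estimated correlation).

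In NOD/ShiLtJ, Crym, a cytosolic thyroid hormone-binding protein, was at 5.65 ± 0.245 CPM against 192 ± 41.4, a log2 fold change of -5.06 (SE 0.0967, edgeR adjusted p = 7.4e-44). Nudt19, a coenzyme A hydrolase, fell by 1.37, Arntl2, a paralogue of the clock gene Arntl, by 1.10, and Cdhr1, a cadherin of photoreceptors, by 2.25 on the log2 scale. Among the rises, Ccl28, a chemokine, was at 9.93 ± 2.38 against 1.45 ± 1.92. Glp2r, a receptor of the glucagon family, was at 10.8 ± 3.20 against 1.90 ± 1.45. Serpinf1, which encodes pigment epithelium-derived factor, was at 22.6 ± 2.69 against 10.6 ± 3.13. Oligodendrocyte markers were higher as a set (median log2 0.40, 11 of 12 members higher at any fold, camera adjusted p = 4.18e-05, adjusted p = 0.813 with an estimated correlation). So were mitochondrial genome genes (camera 1.13e-05, adjusted p = 0.699 with an estimated correlation), microglia markers (0.00244, adjusted p = 0.699 with an estimated correlation) and complement genes (0.0121, adjusted p = 0.598 with an estimated correlation).

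In A/J, Baiap2l1, an actin-binding adaptor of epithelia, was at 36.2 ± 7.61 CPM against 1.40 ± 1.07 (log2 4.80, edgeR adjusted p = 1.04e-25). Glo1 (glyoxalase, at a locus known to be duplicated in some inbred strains) was at 387 ± 13.8 against 156 ± 64.5 (log2 1.42, edgeR adjusted p = 2.6e-48). Falls included Dnajc10, a disulfide reductase of the endoplasmic reticulum, at 31.7 ± 1.46 against 83.6 ± 8.43 (log2 -1.39, edgeR adjusted p = 3.74e-45). Plch2, a phospholipase C, fell by 1.48 and Opcml, an opioid-binding cell adhesion molecule, fell by 1.16 on the log2 scale. Ccl27a (6.59 ± 1.48 against 26.7 ± 3.98) and Pcdhga11 are uncertain because of copies. Microglia markers were higher as a set (median log2 0.32, 11 of 12 members at any fold, camera adjusted p = 4.18e-05, adjusted p = 0.598 with an estimated correlation), and A/J male 2, which stood apart, lay 0.188 above the other 3 males in them. Genes of textbook strain variants were higher with 3 of 15 members (camera 0.00142, adjusted p = 0.0379 with an estimated correlation). Mitochondrial genome genes were lower as a set (0.00802, adjusted p = 0.999 with an estimated correlation).

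In CAST/EiJ, Pon2, a paraoxonase of the inner mitochondrial membrane, was at 1.73 ± 0.197 CPM against 32.6 ± 6.61 (log2 -4.21, edgeR adjusted p = 4.87e-48). Fam213b, a prostamide synthase, was at 0.254 ± 0.354 against 40.2 ± 9.48 (log2 -7.36, edgeR adjusted p = 1.8e-38). Kcng4, a modulatory potassium channel subunit, was at 0.251 ± 0.138 against 6.68 ± 1.67. Dsp, a desmosomal protein that marks dentate granule neurons, was at 2.65 ± 1.83 against 48.6 ± 19.7 (log2 -4.03). PWK/PhJ had 11.8 ± 2.29 and the 6 other strains 39.8 to 69.8. Among the rises, Tas1r1, a taste receptor subunit, was at 27.7 ± 6.82 against 1.79 ± 0.530 (log2 3.97, edgeR adjusted p = 2.11e-46). Cyp2c70, a cytochrome P450 of bile acid metabolism with close paralogs, was at 4.11 ± 0.578 against 0.00551 ± 0.0147. The ribosomal protein gene Rpl9 was at 216 ± 14.9 against 16.4 ± 4.31 while its pseudogene Rpl9-ps6 was at 6.71 ± 2.0 against 224 ± 31.8. Both are uncertain, like Eno1b, Ftl1-ps1 and Srp54c. Of the 699 higher genes 205, and of the 908 lower genes 144, had all 8 libraries outside all others. As sets, oligodendrocyte markers were lower (9 of 12 members at any fold, camera adjusted p = 0.0143, adjusted p = 0.999 with an estimated correlation) and astrocyte markers higher (0.0175, adjusted p = 0.598 with an estimated correlation).

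In PWK/PhJ, Mttp, the microsomal triglyceride transfer protein, was at 0.848 ± 0.142 CPM against 14.2 ± 4.76 (log2 -3.93, edgeR adjusted p = 4.74e-44). Lag3, an inhibitory immune receptor, was at 0.169 ± 0.0689 against 4.09 ± 2.52 (log2 -4.21). Zfp605, a zinc finger gene of a clustered family, was at 0.0597 ± 0.0530 against 12.8 ± 1.96 (edgeR adjusted p = 5.33e-37) and is uncertain. Lefty2, a TGF-beta family ligand, rose to 16.6 ± 1.51 from 1.13 ± 0.554 in the other strains (log2 4.22, edgeR adjusted p = 2.18e-41). Lpcat2b, a lysophospholipid acyltransferase, was at 5.54 ± 0.881 against 0.0307 ± 0.0387. Hba-a1 (75.9 ± 12), Nutf2-ps1 and AK157302 are uncertain because of copies. Of the 652 higher genes 171, and of the 973 lower genes 136, had all 8 libraries outside all others. Protein genes of the mitochondrial genome were lower as a set (median log2 -0.64, 12 of 13 members at any fold and 4 with the fold minimum, camera adjusted p = 1.7e-06, adjusted p = 0.636 with an estimated correlation). For these genes a loss of reads to mismatches with the reference was not excluded. Oligodendrocyte markers were also lower (median log2 -0.43, 12 of 12 members at any fold, camera 0.00293, adjusted p = 0.992 with an estimated correlation).

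In NZO/HlLtJ, Npsr1, the receptor of neuropeptide S, was at 8.06 ± 0.807 CPM against 1.52 ± 1.15. Aldh1a3, an enzyme of retinoic acid synthesis, was at 4.95 ± 0.83 against 1.0 ± 0.529. Noc2l, a nucleolar inhibitor of histone acetylation, was at 214 ± 10.4 against 71.9 ± 16.7 (log2 1.61, edgeR adjusted p = 5.42e-47). Serpina3n was at 40.5 ± 2.87 against 129.5 ± 79.3 (log2 -1.42). Pccb, a subunit of propionyl-CoA carboxylase, was at 23.3 ± 0.814 against 53.4 ± 12.9 (log2 -1.15). Actbl2 and Gstm5 (43.0 ± 4.82 against 121 ± 26.9) have close paralogs and are uncertain. Endothelial and mural cell markers were higher as a set (camera adjusted p = 0.00265, adjusted p = 0.598 with an estimated correlation), as were MHC class I genes (0.0132, adjusted p = 0.903 with an estimated correlation), and CA1 markers were lower (0.0199, adjusted p = 0.598 with an estimated correlation).

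In WSB/EiJ, Ly6c1, a surface protein of endothelial cells with a close paralog, was at 0.103 ± 0.0766 CPM against 23.7 ± 4.57 (edgeR adjusted p = 4.46e-44) and is uncertain for that reason. Cwc22, a splicing factor gene known to be amplified in some wild-derived mice, was at 629 ± 55.1 against 19.5 ± 2.61 (log2 5.02, SE 0.0309, edgeR adjusted p = 5.17e-71), and is uncertain because of its copies. Aldh3b2, an aldehyde dehydrogenase, was at 37.6 ± 4.85 against 1.29 ± 0.685 (log2 5.01). Il1f9, an interleukin of the IL-1 family, was at 10.5 ± 1.46 against 1.55 ± 1.29. Tmprss6, a membrane protease that controls iron uptake, was at 8.95 ± 1.66 against 1.28 ± 0.952. Tmem114 fell to 0.440 ± 0.160 from 6.07 ± 5.04 in the other strains. The zinc finger genes Zfp738, Zfp967 and Zfp973 and Pcdha7 also fell and are uncertain as members of clustered families. Mitochondrial genome genes were higher as a set (13 of 13 members at any fold, camera adjusted p = 4.24e-07, adjusted p = 0.604 with an estimated correlation). So were CA1 markers (camera 0.0386, adjusted p = 0.613 with an estimated correlation). Microglia markers were lower (9 members at any fold, 0.000182, adjusted p = 0.598 with an estimated correlation), as were opioid, dopamine and endocannabinoid genes (0.0424, adjusted p = 0.343 with an estimated correlation).

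Further list calls at the preset correlation concerned C57BL/6J and CAST/EiJ. In C57BL/6J, dentate granule neuron markers (0.00147, adjusted p = 0.604 with an estimated correlation), endothelial and mural cell markers (0.00527, adjusted p = 0.598 with an estimated correlation) and mitochondrial genome genes (1.71e-07, adjusted p = 0.598 with an estimated correlation) were higher by camera. So were ribosomal protein genes (0.00648, adjusted p = 0.999 with an estimated correlation) and microglia markers (0.0423, adjusted p = 0.918 with an estimated correlation), and the last had an adjusted p of 0.0629 with the choroid plexus score as a covariate. C57BL/6J male 4, which stood apart, lay above the other 3 males by 0.507 in mitochondrial genome genes, 0.344 in ribosomal protein genes, 0.187 in endothelial and mural markers and 0.113 in microglia markers. It lay 0.302 below them in dentate granule neuron markers. Mitochondrial genome genes were lower in CAST/EiJ (camera adjusted p = 0.00249, adjusted p = 0.979 with an estimated correlation), where a loss of reads to mismatches with the reference was not excluded. Over all contrasts, camera called 38 of 333 pairs of list and contrast, and with an estimated correlation 3 held. These were the X and Y lists in the comparison of the sexes and textbook strain variants in A/J (0.0379). Median, mean and test had the same sign in all 38. Permuted sample labels gave 38 or more such calls in 96 of 100 splits, the real one included. Apart from the X and Y lists, these calls therefore describe direction in these libraries and are not evidence beyond chance.

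Among the fixed lists, cell type markers of the hippocampus differed among strains member by member. Counts are of tested members past the F test with a range of at least 1, and counts adjusted over the list alone were the same except where given. Dentate granule neuron markers differed in 6 of 11 and CA1 markers in 4 of 9, with CA2 at 3 of 8, CA3 at 3 of 10, interneurons at 2 of 12 and neurogenesis at 3 of 10. C1ql2, a synaptic organiser of mossy fibres, was at 109 ± 11.2 CPM in C57BL/6J and 33.4 to 58.4 in the other strains. Lct, a dentate marker, was at 139 ± 26.3 in CAST/EiJ and 24.5 ± 7.10 in NOD/ShiLtJ. Tdo2, which degrades tryptophan, was at 0.865 ± 0.183 in PWK/PhJ against 5.60 to 7.89. Wfs1, an endoplasmic reticulum protein marking CA1, was at 476 ± 103 in CAST/EiJ and 128 ± 21.6 in NZO/HlLtJ. Bok, a BCL2 family gene, was at 102 ± 13.8 in WSB/EiJ and 37.7 ± 3.58 in PWK/PhJ. Dlx6os1, an antisense transcript of interneurons whose reads cannot be separated from overlapping genes, was at 34 ± 3.46 in WSB/EiJ and 9.36 ± 1.92 in CAST/EiJ. Npy, the neuropeptide Y gene, was at 43.7 ± 8.63 in WSB/EiJ and 21.5 ± 1.41 in NOD/ShiLtJ. Igfbpl1, a marker of young neurons, was at 4.27 ± 1.86 in CAST/EiJ and 1.25 ± 0.742 in PWK/PhJ.

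Glial and vascular markers differed among strains too. Astrocyte markers differed in 1 of 10, oligodendrocyte markers in 3 of 12, their precursors in 0 of 8 (7 of 8 by the same edgeR test without the fold minimum), microglia markers in 3 of 12 and endothelial and mural markers in 2 of 12. S100b, a calcium-binding protein of astrocytes, was at 244.5 ± 13.8 CPM in PWK/PhJ and 85.1 to 136 in the other strains. Mobp, a myelin protein, was at 707 ± 117 in A/J and 324 ± 23.8 in CAST/EiJ. Aspa, the aspartoacylase of oligodendrocytes, was at 17.2 ± 3.39 in NOD/ShiLtJ and 6.93 ± 1.17 in CAST/EiJ. Trem2, a microglial lipid receptor, was at 14 ± 2.42 in NOD/ShiLtJ and 5.61 ± 0.670 in CAST/EiJ. Ctss, a lysosomal protease, was at 73.4 ± 3.78 in PWK/PhJ and 33.0 ± 2.75 in CAST/EiJ.

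Markers of tissue next to the hippocampus also varied. Meningeal fibroblast markers differed in 6 of 8, thalamus and habenula markers in 4 of 10, and striatum markers in 5 of 10. Neocortex markers differed in 2 of 9, ependymal markers in 3 of 8, blood markers in 3 of 5 and choroid plexus markers in 2 of 12 (0 adjusted over the list alone). The choroid plexus transcript Ttr, a thyroid hormone carrier, was at 1568 ± 1494 CPM in CAST/EiJ and 378 ± 620 in PWK/PhJ, and its strain difference did not pass the test (edgeR adjusted p = 0.852). Ogn, a meningeal proteoglycan, was at 12.9 ± 3.10 in NZO/HlLtJ and 4.56 ± 1.52 in CAST/EiJ, and Igf2 at 154 ± 73.5 in NZO/HlLtJ and 39.5 ± 33.2 in PWK/PhJ. Penk, the proenkephalin gene abundant in striatum, was at 83.0 ± 4.58 in PWK/PhJ and 17.8 ± 4.52 in A/J. Prkcd, a kinase abundant in thalamus, was at 51.9 ± 8.62 in NOD/ShiLtJ and 24.3 ± 6.07 in C57BL/6J. Rspo1, a Wnt agonist in the neocortex list, was at 9.71 ± 2.33 in CAST/EiJ and 0.850 ± 0.367 in C57BL/6J.

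Immune lists held many strain differences. MHC class II genes differed in 6 of 8, interferon-stimulated genes in 13 of 18, complement genes in 8 of 11 and MHC class I and antigen processing genes in 9 of 16. Cd74, the invariant chain, was at 6.74 ± 3.08 CPM in NZO/HlLtJ and 1.11 ± 0.598 in PWK/PhJ. Ifit3, an interferon-induced gene, was at 9.10 ± 2.97 in C57BL/6J and 1.04 ± 0.260 in PWK/PhJ. Ifit2 was at 22.1 ± 1.84 in PWK/PhJ and 6.08 to 8.28 elsewhere and Ifi27 at 5.30 ± 0.733 in PWK/PhJ and 23.8 to 32.4 elsewhere. C3, the central complement component, was at 11.4 ± 1.5 in WSB/EiJ and 8.12 ± 1.69 in CAST/EiJ against 1.13 to 3.68 in the other strains. C4b was at 83.0 ± 9.04 in NZO/HlLtJ and 12.1 ± 1.51 in WSB/EiJ, and H2-D1 at 4.54 ± 0.634 in WSB/EiJ and 13.5 to 37.6 elsewhere. Both belong to duplicated or highly variable families and are uncertain.

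Signalling and metabolic lists differed as follows. Of the glutamate receptor genes, 0 of 22 had a range of at least 1, although 21 passed the edgeR test without that minimum. Gria2, the main AMPA receptor subunit, had strain means of 706 to 825 CPM. GABA-A receptor genes differed in 2 of 13 (Gabra2 and Gabre), opioid, dopamine and endocannabinoid genes in 6 of 19, glutathione and detoxification genes in 12 of 20 and steroid hormone genes in 5 of 12. Th, the rate-limiting enzyme of dopamine synthesis, was at 3.62 ± 0.712 in PWK/PhJ and 0.294 to 0.681 elsewhere. Drd5, a dopamine receptor, was at 17.8 ± 0.729 in C57BL/6J and 4.86 ± 0.462 in PWK/PhJ. Pdyn, the prodynorphin gene, was at 17.2 ± 3.67 in NOD/ShiLtJ and 7.05 ± 1.0 in WSB/EiJ. Star, which brings cholesterol into mitochondria for steroid synthesis, was at 1.81 ± 0.435 in CAST/EiJ, 1.86 ± 0.334 in PWK/PhJ and 2.40 ± 0.403 in WSB/EiJ against 5.80 to 6.24 in the other strains. Hsd11b1, which regenerates corticosterone, was at 41.0 ± 2.80 in CAST/EiJ and 18.0 ± 1.23 in NOD/ShiLtJ. Gsta4 (12.4 ± 1.74 in CAST/EiJ against 38.6 to 56.4) and Gstm7 are uncertain because of paralogs.

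Genes that respond to the state of the animal and housekeeping genes completed the lists. Immediate early genes differed in 5 of 13, glucocorticoid response genes in 2 of 12 and circadian clock genes in 1 of 15. This was Per2, at 58.3 ± 16.1 CPM in CAST/EiJ and 27.5 to 39.6 elsewhere. Arc, a synaptic immediate early gene, was at 185 ± 92.9 in CAST/EiJ and 77.8 to 118 elsewhere. Genes of textbook strain variants differed in 10 of 15, with Alad, an enzyme of haem synthesis, at 47.7 ± 6.68 in A/J and 15.7 ± 1.09 in PWK/PhJ. Mitochondrial genome genes differed in 7 of 13, with mt-Nd1 at 1492 ± 203 in CAST/EiJ and 1551 ± 128 in PWK/PhJ against 2901 to 5022 elsewhere. A loss of reads to mismatches with the reference was not excluded for mitochondrial genes in CAST/EiJ and PWK/PhJ, so their levels there are uncertain. These strains also enter the mean that the set calls of other strains were made against. Nuclear genes of oxidative phosphorylation differed in 5 of 78, ribosomal protein genes in 4 of 77 (Rpl9 among them, uncertain) and Zfp genes in 67 of 376. Y genes differed in 1 of 6 (Uty, whose range comes from female levels of 0.0564 to 0.660 CPM, with males at 12.9 to 18.7) and X escape genes in 0 of 12, of which 11 passed the edgeR test without the fold minimum. In 4 libraries that stood apart from their groups (129S1/SvImJ female 1, A/J male 2, C57BL/6J male 4 and WSB/EiJ female 1), ribosomal protein genes lay 0.34 to 0.64 and nuclear oxidative phosphorylation genes 0.30 to 0.63 above the other 3 libraries of the group on the log2 scale.

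The sexes differed in few genes over all strains (n = 32 against 32). A total of 29 genes passed the edgeR test, 20 higher and 9 lower in females, with about 920 at an unadjusted p under 0.05. Of the higher genes 9 were X-linked and 10 autosomal with 1 on an unplaced scaffold, and of the lower 6 were Y-linked and 3 autosomal. Xist, the RNA that silences the inactive X, was at 396 ± 114 CPM in females and 0.856 ± 0.230 in males. In the X escape list 8 of 12 members rose (10 adjusted over the list alone), including the translation factor Eif2s3x (188 ± 19.5 against 124 ± 10.6, log2 0.60, SE 0.017, edgeR adjusted p = 4.97e-36), the histone demethylases Kdm6a (log2 0.45) and Kdm5c (0.38), and the RNA helicase Ddx3x (0.33). In the Y list 5 of 6 members fell, with Ddx3y at 55.1 ± 5.18 in males, Kdm5d at 19.6 ± 3.56 and Uty at 15.3 ± 2.32, and Usp9y did not pass. Camera called both lists, and the calls held with an estimated correlation (7.79e-18 for X and 7.46e-28 for Y).

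Autosomal sex differences were small. Ogdhl, a mitochondrial dehydrogenase of brain, was at 99.5 ± 12.5 CPM in females and 92.8 ± 18.1 in males (log2 0.11, edgeR adjusted p = 0.000979). Fgfr3, a growth factor receptor of astrocytes, was at 128 ± 32.5 and 117 ± 29.6 (log2 0.13, 0.00352). Selenop, the selenium carrier, was at 251 ± 72.5 and 231 ± 68.0 (log2 0.12, 0.0225, and 0.0733 without NOD/ShiLtJ females 1 and 2). Tob2, an antiproliferative regulator, rose by 0.15 and Zfp772 by 0.23 on the log2 scale. Hif3a, a hypoxia-inducible factor subunit, was at 5.75 ± 2.99 and 3.86 ± 1.87 (log2 0.66, SE 0.138, edgeR adjusted p = 0.012). Its adjusted p was 0.0509 in the additive model and 0.0587 without NOD/ShiLtJ females 1 and 2. Fabp7, a fatty acid-binding protein of radial glia and astrocytes, was at 18.8 ± 7.11 and 24.2 ± 9.82 (log2 -0.31, 0.0491). Kbtbd7, a ubiquitin ligase adaptor, fell by 0.21 on the log2 scale (3.11e-05), with a call in 1 strain, WSB/EiJ, and this sign in 5 of 8 strains. Calls close to the threshold depended on single libraries. The call for Fabp7 was lost in 45 of 64 omissions (up to 0.0925 without CAST/EiJ male 1) and for Rapgef3 in 29 (up to 0.0731 without 129S1/SvImJ female 3). That for Kirrel2 was lost in 24 (up to 0.0719 without C57BL/6J male 2) and for Pcdhb3 in 24 (up to 0.0651 without PWK/PhJ male 2). The same calls ended without NOD/ShiLtJ females 1 and 2 (0.0535 to 0.0901) and with autosomal genes only (0.0751 to 0.104), where 13 autosomal calls became 9. The count of 29 rose to 47 without 129S1/SvImJ female 1. Immediate early genes were higher in females as a set by camera (2.9e-05, adjusted p = 0.788 with an estimated correlation) although 0 members passed the edgeR test (1 adjusted over the list alone). The same held for glucocorticoid response genes (0.00151, adjusted p = 0.698 with an estimated correlation), where 0 members passed and 4 higher and 1 lower did so adjusted over the list alone, and for clock genes (0.00293, adjusted p = 0.604 with an estimated correlation). MHC class I genes were higher too (0.000881, adjusted p = 0.699 with an estimated correlation), with 0 members past the test and 3 adjusted over the list alone. Microglia markers (0.0199, adjusted p = 0.85 with an estimated correlation) and mitochondrial genome genes (0.00808, adjusted p = 0.999 with an estimated correlation) were lower. Single strains weighed on these lists. The median log2 difference was 0.548 for glucocorticoid response genes and 0.271 for clock genes in NOD/ShiLtJ, against -0.0412 to 0.154 and -0.0635 to 0.0653 in the other strains. For MHC class I genes it was 0.247 in 129S1/SvImJ and 0.235 in NOD/ShiLtJ against -0.0825 to 0.0988. For mitochondrial genome genes it was -0.263 in CAST/EiJ against -0.102 to 0.0657, and for immediate early genes -0.195 in C57BL/6J against 0.0587 to 0.314.

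Within single strains (n = 4 against 4), most called genes were X-linked or Y-linked in each strain but NOD/ShiLtJ. The counts were 10 in C57BL/6J, 11 in 129S1/SvImJ, 16 in A/J, 18 in CAST/EiJ, 10 in PWK/PhJ, 10 in NZO/HlLtJ and 10 in WSB/EiJ, and 123 in NOD/ShiLtJ. In the model of all samples no autosomal gene was called by edgeR in C57BL/6J, 129S1/SvImJ and NZO/HlLtJ, where a test of autosomal genes alone gave 0. Over all genes, 419, 1497 and 9.5e+02 had an unadjusted p under 0.05 there, and DESeq2 gave totals of 12, 17 and 11. A fit of the 8 NZO/HlLtJ samples alone called 2 autosomal genes when these were adjusted alone. In A/J, Prune2, a neuronal BCH domain protein, was at 71.4 ± 8.48 CPM in females and 47.0 ± 7.03 in males (log2 0.60, edgeR adjusted p = 1.36e-06). The neuropeptide genes Avp (6.29 ± 12.4 against 0.105 ± 0.177) and Oxt (7.51 ± 14.9 against 0.15 ± 0.210) passed there with A/J female 3 at 24.9 and 29.8 CPM, and without that library Avp had an adjusted p of 0.993 and Oxt of 0.776. With autosomal genes only these were 0.122 and 0.119. In CAST/EiJ, Inhbb, an activin subunit, was at 8.97 ± 2.08 and 5.19 ± 0.899 (log2 0.79, edgeR adjusted p = 0.000178). C4b, a complement component with a near-identical copy, was at 44.8 ± 2.25 and 71.7 ± 5.52 (log2 -0.68, 7.88e-05). Gfap, the astrocyte filament protein, was at 491 ± 22.8 and 624 ± 43.0 (log2 -0.35, 0.0427, and 0.0776 with autosomal genes only). Ifit3b, an interferon-induced gene with close paralogs, was at 0.418 and 1.46 (log2 -1.80, 0.00617). The interferon list in CAST/EiJ had 1 member lower (6 adjusted over the list alone) of 18, and the mitochondrial genome list 0 (9 lower adjusted over the list alone) of 13. Sex cannot be separated from the block of title numbers in CAST/EiJ, and its count was 46 without CAST/EiJ male 3 and 45 without CAST/EiJ female 1. The A/J count was 10 without A/J male 2. Near the threshold, Zfp553 in CAST/EiJ (log2 0.31, 0.0278) reached an adjusted p of 0.405 without CAST/EiJ male 1 and Ccnk in PWK/PhJ (21.7 ± 0.967 against 18.2 ± 0.345, 0.0474) one of 0.402 without PWK/PhJ male 2, and these calls were lost in 5 and 7 of 8 omissions. With autosomal genes only the adjusted p was 0.0776 for Zfp553 and 0.341 for Ccnk. Among the X and Y genes, calls for Kdm5c were lost in 7 of 8 omissions in A/J, 4 in PWK/PhJ and 3 in NZO/HlLtJ. Those for Kdm6a were lost in 3 in A/J, 4 in CAST/EiJ and 5 in NZO/HlLtJ. In 129S1/SvImJ the call for Ddx3x was lost in 6 and that for Pbdc1 in 4, with Pbdc1 weakest without female 1. The call for Uba1y in NZO/HlLtJ was lost in 4 (up to 0.134). Without A/J male 2 the adjusted p of Kdm5c in A/J was 0.936.

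In NOD/ShiLtJ, 92 genes were higher and 31 lower in females, of which 10 were X-linked, 5 Y-linked and 108 autosomal. Rises included those of Plin4, a lipid droplet protein (14.1 ± 18.6 against 1.91 ± 0.219 CPM), Rtp1, a receptor transport protein (3.77 ± 4.58 against 0.565 ± 0.179), Etnppl, an astrocyte phospholyase (12 ± 14.6 against 2.64 ± 0.563), and Hif3a (6.25 ± 6.60 against 1.47 ± 0.116). Of 12 glucocorticoid response genes 3 rose (9 adjusted over the list alone, median log2 0.55). Of 15 circadian clock genes 4 rose (8 adjusted over the list alone). These were Per1 (log2 0.62, 0.00937), Ciart (1.16, 0.00751), Bhlhe41 (0.41, 0.0044) and Cry2 (0.33, 0.0142). Cyp51, a sterol demethylase, and Msmo1, a sterol oxidase, were chosen after their values were seen. Cyp51 was at 44.8 ± 10.7 in females and 60.8 ± 1.88 in males (0.00656) and Msmo1 at 47.3 ± 13 and 65.9 ± 3.52 (0.0406). Female 1 stood apart in these examples, and female 2 less clearly. Hif3a was at 15.9 in female 1 and 4.98 in female 2, against 2.05 and 2.03 in females 3 and 4. Map3k6 was at 6.40 in female 1 and 0.877 to 1.65 in the other females. Fkbp5, a glucocorticoid-induced co-chaperone, was at 121 in female 1, 75.6 in female 2 and 69.3 and 65.5 in females 3 and 4. The count was 8 without NOD/ShiLtJ female 1, 39 without male 1, 52 without male 3, 42 without male 4, 355 without female 3 and 445 without female 4. Without female 1, Plin4 had an adjusted p of 0.629, Rtp1 of 0.572 and Hif3a of 0.528, Etnppl of 0.837 and Map3k6 of 0.834. Females 1 and 2 had the choroid plexus transcript Ttr at 2351 and 2742 CPM against 32.1 and 29.5 in females 3 and 4, with the males at 463 to 2277.

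**Figure D4:**
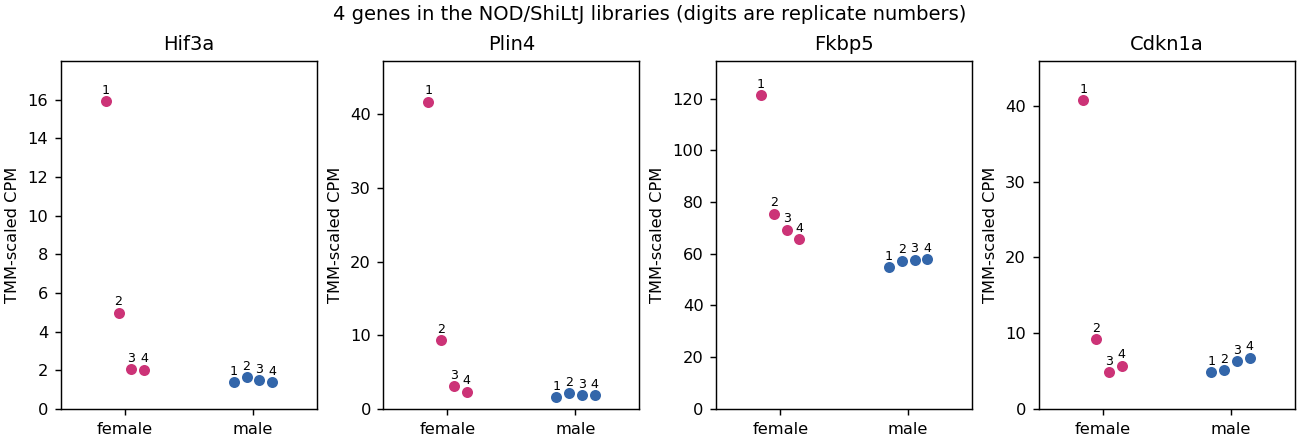
Level in CPM (vertical axes) of 4 genes in the 8 NOD/ShiLtJ libraries, by sex, with digits giving the replicate number. Female 1 lies highest for Hif3a (15.9 CPM), followed by female 2 (4.98), while females 3 (2.05) and 4 (2.03) lie close to the males.

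A test of the interaction asked whether the sex difference varied among strains, and 8 genes passed (edgeR, 1859 at an unadjusted p under 0.05). This count was 67 with DESeq2, 17 without the libraries that stand apart and 3 without CAST/EiJ. Kbtbd7 was at 15.2 ± 1.79 CPM in WSB/EiJ females and 47.7 ± 11.4 in WSB/EiJ males, with means of 56.9 to 65.3 in the other 14 groups. Its sex difference was -1.65 (log2, SE 0.0996) in WSB/EiJ and -0.10 to 0.10 elsewhere (interaction adjusted p = 6.56e-14). Prune2 was higher in females of A/J by a log2 of 0.60 against -0.10 to 0.13 (0.00222). C4b differed by -0.68 in CAST/EiJ and 0.29 in PWK/PhJ (0.00466). Bhlhe41, a transcriptional repressor of the clock, differed by 0.41 in NOD/ShiLtJ and -0.34 in CAST/EiJ (0.0217). Acap3, a GTPase-activating protein, was at 185 ± 23.3 and 148 ± 1.90 in NOD/ShiLtJ females and males (0.035). Gbx1, a homeobox gene at low counts (0.0334 CPM in CAST/EiJ females and 1.42 ± 0.956 in males), passed with 0.0155. Uty passed with 2.7e-05 on female levels under 1 CPM (0.660 ± 0.387 in CAST/EiJ females and 0.0564 in 129S1/SvImJ females). Without CAST/EiJ the adjusted p was 0.0515 for Uty, 0.622 for C4b, 0.532 for Gbx1, 0.392 for Bhlhe41 and 0.158 for Acap3. With autosomal genes only it was 0.057 for Acap3. Leaving out NOD/ShiLtJ female 1 gave 0.14 for Bhlhe41 and 0.281 for Acap3, and leaving out CAST/EiJ female 3 gave 0.0792 for Gbx1 and a count of 5.

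**Figure D5:**
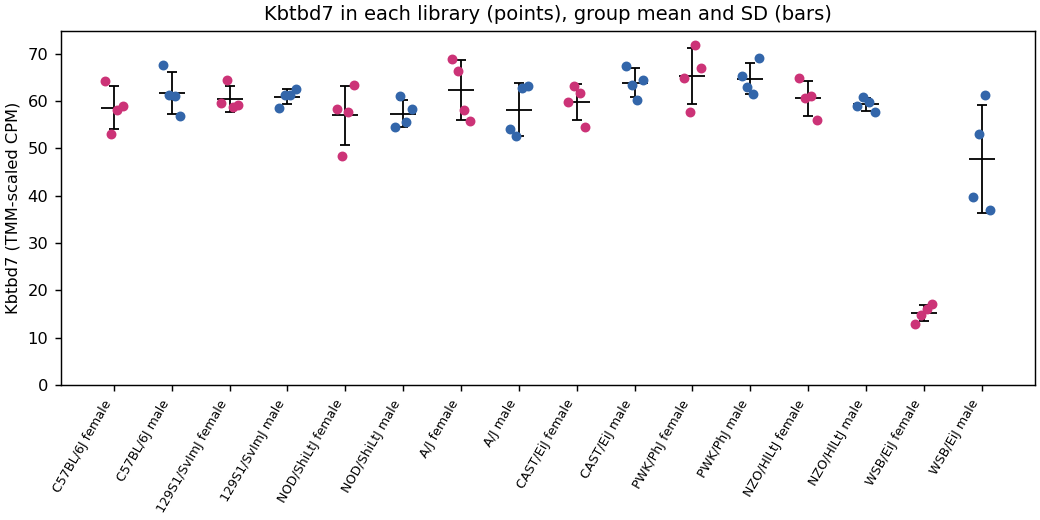
Kbtbd7 level in CPM (vertical axis) in each library of the 16 groups of strain and sex, with 4 points per group. The WSB/EiJ females (mean 15.2 CPM) lie below all other libraries, the WSB/EiJ males average 47.7 CPM, and the other 14 groups have means of 56.9 to 65.3 CPM.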

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

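The tests of a single library, of the time of day, of mislabelled libraries, of the list calls with an estimated correlation and of autosomal genes in other splits, and the alternatives without the libraries that stand apart and without NOD/ShiLtJ females 1 and 2, were chosen only after the result was seen. Groups of 4 were checked for a library far from its other 3, which chance gives in about 1 in 20 checks. The checks covered library measures in the 16 groups and autosomal genes named for a sex difference within a strain. Such a library was found in 13 of 110 checks against 5.5 expected by chance. The checks share libraries and the genes were picked from these data, so 5.5 is only a rough guide.

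On the second component of the within-group residuals, 129S1/SvImJ female 1 scored 44.72 against -19.92 to -10.24 in its group. A/J male 2 scored 39.52 against -14.64 to -10.31. CAST/EiJ female 4 scored 18.32 against -7.917 to -4.024 and PWK/PhJ male 4 scored 13.48 against -4.61 to -4.352. The mean log2 CPM of choroid plexus markers was 4.736 in 129S1/SvImJ male 4 against 0.3269 to 0.6192 in its group, and 1.097 in CAST/EiJ male 4 against 4.274 to 4.695. A/J male 1 had 19.05 M counts in total against 21.64 to 22.13 M. Among named genes, Avp was at 24.87 CPM and Oxt at 29.84 in A/J female 3 against at most 0.1437 and 0.09581 in the other A/J females. Avp was at 0.368 in A/J male 4 against at most 0.05113. Map3k6 was at 6.398 CPM in NOD/ShiLtJ female 1 against 0.8772 to 1.645, Inhbb at 5.881 in CAST/EiJ female 1 against 9.631 to 10.39. Gbx1 was at 0 in CAST/EiJ female 4 against 0.0428 to 0.04694, where all 4 values rest on a few counts.

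The sex difference varied among strains by the edgeR interaction test for Kbtbd7 (adjusted p = 6.56e-14), Uty (2.7e-05), Prune2 (0.00222), C4b (0.00466), Gbx1 (0.0155), Bhlhe41 (0.0217) and Acap3 (0.035).

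Kbtbd7 was lower in WSB/EiJ females than in WSB/EiJ males. Mislabelled libraries are argued against, since 0 of the 8 WSB/EiJ libraries had Xist and Ddx3y levels of the other sex. A change of this size (log2 -1.65) over the neighbouring genes is argued against too, since 1 of the 10 nearest tested genes (Gm49015, log2 -1.30) was lower at an unadjusted p under 0.05. By sign, 8 of the 10 were lower, among them Vwa8 (-0.169, edgeR unadjusted p = 0.0534), Elf1 (-0.232, edgeR unadjusted p = 0.0532) and Kbtbd6 (-0.394), so a smaller shift of the region stays open. A variant of Kbtbd7 carried by some animals of the strain, or a real effect of sex in this strain, may underlie it, and neither was tested.

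Females and males of NOD/ShiLtJ differed in 123 genes. The count rests on single libraries, with 8 genes without female 1, but also 39, 52 and 42 without males 1, 3 and 4, and 9 in a fit of the strain's 8 samples alone. Of the 8 single omissions 6 moved the count by more than 1.5 times, and those of female 2 and male 2 did not. A loss of power with fewer females is argued against as the reason for the fall without female 1. Without females 3 and 4, 355 and 445 genes were called. Whether female 1 is the only source stays open, since omissions of males lowered the count as well. With the choroid plexus score as a covariate 150 genes were called, so the count did not fall as choroid plexus in the dissection would predict. Whether the 123 genes were among them was not compared as a set, and the covariate had a single slope for all strains. Choroid plexus as the cause is therefore not excluded. A shift in the time of day of collection cannot be told apart from other states of the animal, since of the 12 clock genes other than Per1, Ciart and Bhlhe41 only 1 passed the test over all genes and 5 passed adjusted over the list alone. The first count alone had been read as arguing against it, and the rule was changed to leave it open after both counts were seen, as was that for a single library. An acute stress response in female 1, and less clearly in female 2, may be another source, as glucocorticoid response genes were among the rises. The labels hold nothing that tests it.

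More genes were lower than higher in CAST/EiJ and PWK/PhJ. A general loss of reads to mismatches with the reference genome, at small changes as well as large, could not be decided. Among genes past the test with a log2 change of 0.2 to 1 the share lower was 48.9% in CAST/EiJ and 50.9% in PWK/PhJ. It was 32.8% to 50.1% in the other strains. The scaling held the median log2 change at -0.000956 in CAST/EiJ and -0.00284 in PWK/PhJ, which draws this share toward even. CAST/EiJ and PWK/PhJ also enter the mean that the other strains are set against, so those are no independent yardstick. A loss equal in all genes would be scaled away and is not tested, and a loss confined to strongly diverged genes stays open. With a mean of at least 50 counts 57.6% of called genes were lower in CAST/EiJ and 65.1% in PWK/PhJ. That mean was taken over all libraries, so it keeps genes lost in a single strain more readily than genes gained in it. The share lower fell in no strain under it, and rose from 49.2% to 60.8% in WSB/EiJ and from 29.7% to 39.0% in NOD/ShiLtJ. Low-count genes as the source can therefore not be judged by this filter. True differences of the wild-derived strains may underlie the balance as well and were not tested apart from such losses. Without a count filter the balance turned, with 1626 higher and 1248 lower genes in CAST/EiJ and 1586 and 1328 in PWK/PhJ.

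Other splits of the samples were drawn to ask how often the counts arise without the real groups. Chance can be excluded for the F test over strains (4569 genes, at most 26 in the other 29 splits, so 1 of 30 as large) and for pairs of strains (1096.5, at most 0, 1 of 30). For single strains, counts in the splits' own fit were 476 for C57BL/6J, 381 for 129S1/SvImJ, 426 for NOD/ShiLtJ, 395 for A/J, 1617 for CAST/EiJ, 1613 for PWK/PhJ, 388 for NZO/HlLtJ and 731 for WSB/EiJ. The highest other of 93 splits gave 521. That split held 5 CAST/EiJ libraries in its set of 8, which points to a structure of the samples, namely strain itself, and the next highest gave 4. With 1 of 93 splits as large, chance can be excluded for CAST/EiJ, PWK/PhJ and WSB/EiJ. For the other strains 2 of 93 were as large, which is under the 1 in 20 set beforehand. As the split with 521 exceeded their counts, these splits alone do not exclude chance for the size of those counts. Chance can be excluded for female against male (29 genes, highest other 2, 1 of 80). The same holds for autosomal genes adjusted alone within the fit of all genes (8 genes, highest other 2, 1 of 80), where a fit of autosomal genes only gave 9. For the interaction 2 of 80 splits were as large, which is under the 1 in 20 set beforehand. As another split gave 14 genes against the real 8, chance is not excluded for that count. Within strains, fitted on 8 samples with 35 splits, it can be excluded for NOD/ShiLtJ (9 genes, highest other 1), A/J (6 and 0), NZO/HlLtJ (12 and 4) and WSB/EiJ (8 and 1), with 1 split as large in each. It cannot be excluded for C57BL/6J (7 genes, highest other 20, 2 of 35), 129S1/SvImJ (7 and 30, 3 of 35), CAST/EiJ (20 and 97, 3 of 35) and PWK/PhJ (14 and 89, 3 of 35), where splits with several times the real count point to a structure of the samples beside sex. In C57BL/6J and 129S1/SvImJ the splits concern the number of genes alone. The genes called there with all samples in the model were all X-linked or Y-linked (10 and 11, 0 autosomal), and the splits do not test them singly. As 0 of the 64 libraries had Xist and Ddx3y levels of the other sex, the sex labels are not put in doubt. Calls for Ddx3x and Pbdc1 in 129S1/SvImJ were lost in 6 and 4 of 8 omissions, so not every such call is secure. All these counts within strains include X and Y genes, which follow sex in any case. For autosomal genes adjusted alone chance cannot be excluded in NOD/ShiLtJ (1 gene, highest other 1, 3 of 35), CAST/EiJ (2 and 97, 6 of 35), PWK/PhJ (1 and 87, 4 of 35), NZO/HlLtJ (2 and 4, 3 of 35) and WSB/EiJ (1 and 1, 2 of 35). In C57BL/6J, 129S1/SvImJ and A/J these fits gave no autosomal call to test. The splits of NOD/ShiLtJ therefore do not test the 123 genes of the model of all samples. In CAST/EiJ the split with 97 set males 1, 2 and 4 with female 1 against the rest. For the gene lists chance cannot be excluded at the preset correlation, with 38 calls against at most 86 and 96 of 100 splits as large. It can be excluded for the number of calls with an estimated correlation (3, against at most 2 in the other splits, 1 of 100 as large). As the X and Y lists make up 2 of these, this does not exclude it for the call in A/J.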

How the results depend on the processing

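The alternatives without the libraries that stand apart and without NOD/ShiLtJ females 1 and 2 were chosen only after the result was seen. Counts are given in the order C57BL/6J, 129S1/SvImJ, NOD/ShiLtJ, A/J, CAST/EiJ, PWK/PhJ, NZO/HlLtJ and WSB/EiJ for each strain against the others. By construction, the fold minimum set the counts, which were 6599, 5608, 6890, 5889, 9873, 10030, 6610 and 7350 with none. They were 160, 146, 172, 164, 555, 555, 153 and 242 with a log2 minimum of 2. They were 1325, 1168, 1561, 1138, 2874, 2914, 1370 and 1542 with no count filter, where more genes were tested. They were 164, 173, 159, 154, 443, 456, 143 and 227 with a mean of at least 50 counts, where fewer were. DESeq2 gave 1029, 9.6e+02, 1126, 945, 2495, 2479 and 1021 for the first 7. It was run on all genes with a count, of which 21514 were given an adjusted p in C57BL/6J. The tool and the genes tested thus changed together, and their parts were not told apart. The F test over strains called 15513 genes without a fold minimum, 1639 with a minimum of 2 and 1686 with a mean of at least 50 counts, and pairs of strains had medians of 6768, 392.5 and 307. Size factors of DESeq2 in place of TMM, the choroid plexus covariate, the additive model and the libraries that stand apart moved none of these counts by 1.5 times, and neither did any single omission where it was run. Single omissions were not run for pairs of strains.

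For female against male, the 29 genes became 9 with autosomal genes only, 48 with DESeq2, and 25 (without NOD/ShiLtJ male 1) to 47 (without 129S1/SvImJ female 1) in single omissions. Without NOD/ShiLtJ females 1 and 2 the count was 25, of which 23 were shared, with Hif3a, Fabp7, Rapgef3, Kirrel2, Pcdhb3 and Selenop lost. With autosomal genes only, edgeR gave 0 in C57BL/6J (387 at an unadjusted p under 0.05), 0 in 129S1/SvImJ (1459), 0 in PWK/PhJ (657), 0 in NZO/HlLtJ (9.5e+02 over all genes), 1 in A/J, 6 in CAST/EiJ and 2 in WSB/EiJ, and DESeq2, run over all genes, gave 12, 17, 15 and 11 for the first 4. X and Y genes were left out there, and autosomal calls ended too, with 13 becoming 9 over all strains, 4 becoming 1 in A/J, 8 becoming 6 in CAST/EiJ, 108 becoming 96 in NOD/ShiLtJ and 1 becoming 0 in PWK/PhJ. Genes among them were Pcdhb3, Kirrel2, Rapgef3 and Fabp7 over all strains, Avp and Oxt in A/J, Zfp553 and Gfap in CAST/EiJ, Ccnk in PWK/PhJ and 12 in NOD/ShiLtJ (adjusted p up to 0.0549), Fam216b and Txnip among them. Fits of a strain's 8 samples gave 7 in 129S1/SvImJ, 6 in A/J and 9 in NOD/ShiLtJ, and DESeq2 gave 17 in 129S1/SvImJ and 283 in NOD/ShiLtJ. The NOD/ShiLtJ count was also 60 with no count filter, 202 with a mean of at least 50 counts, 402 without the libraries that stand apart and 8 without females 1 and 2, and single omissions gave 8 (female 1) to 445 (female 4). Single omissions gave 10 (male 2) to 17 (female 4) in A/J and 13 (male 1) to 46 (male 3) in CAST/EiJ, where the count was 56 without the libraries that stand apart although none of these is from CAST/EiJ. The interaction had 3 genes without CAST/EiJ, 17 without the libraries that stand apart, 67 with DESeq2 and 5 (without CAST/EiJ female 3) to 12 (without CAST/EiJ female 1) in single omissions. Except where fewer samples or genes entered, the cause was not tested. With DESeq2 both the tool and the genes tested changed. Of 38 list calls 3 held with an estimated correlation. With DESeq2 size factors 38 of the 38 were shared, and with the choroid plexus covariate 37 were.

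For single genes, 6521 of 6855 values kept direction and side of the threshold, 331 were past it no longer and 3 turned. These were Etnppl in NOD/ShiLtJ without females 1 and 2 (log2 -0.3861, adjusted p = 0.962) and, without A/J female 3, Avp (-0.07372, 0.993) and Oxt (-1.033, 0.776). Over the 8 omissions, the log2 change ran from these values to 8.198 for Avp, female versus male in A/J, and 7.155 for Oxt, female versus male in A/J, both without A/J male 4. Of the values past the threshold no longer, 259 came from single omissions, 15 from the fits of 8 samples, 15 from leaving out NOD/ShiLtJ females 1 and 2, 10 from leaving out CAST/EiJ, 10 from autosomal genes only and 9 from no count filter. No paired analysis was possible because the labels give no replicate numbers shared between groups, and the numbers used here follow deposition order. Depth limited genes of a few counts, such as Gbx1 and Uba1y, and intervals of spread between samples do not cover errors of read assignment between strains.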

Other observations

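The alternative without NOD/ShiLtJ females 1 and 2 was chosen only after the result was seen. Further members of the fixed lists differed among strains by the edgeR F test with a range of at least 1, with n = 8 per strain. Trim12a, an antiviral TRIM family gene with close paralogs, was at 2.57 ± 0.398 CPM in C57BL/6J and 0.0382 to 0.0773 in the other strains. Gbp2b, an interferon-induced GTPase, was at 2.32 ± 0.353 in A/J, 1.59 ± 0.374 in 129S1/SvImJ and 0.00464 in C57BL/6J. Cyp11a1, the first enzyme of steroid synthesis, was at 0.0769 in A/J, 0.111 in CAST/EiJ and 0.0770 in NZO/HlLtJ against 0.883 to 1.71 in the other strains. Iyd, which recovers iodide from tyrosine, was at 5.09 ± 0.506 in NOD/ShiLtJ and 0.865 ± 0.234 in PWK/PhJ, and Cd59a, an inhibitor of complement lysis, at 13.6 ± 2.35 and 2.71 ± 0.889 in the same strains. Tac2, a tachykinin of the habenula, was at 4.87 ± 0.626 in NOD/ShiLtJ and 1.51 ± 0.262 in PWK/PhJ. Oprm1, the mu opioid receptor, had its highest level in PWK/PhJ (2.80 ± 0.596). The mitochondrial gene mt-Nd3 was at 81.6 ± 16.2 in CAST/EiJ and 153 ± 17.4 in PWK/PhJ against 600 ± 62.1 in WSB/EiJ. Its levels in CAST/EiJ and PWK/PhJ are uncertain, as reads may be lost to mismatches with the reference there. Col6a1, a collagen of meningeal fibroblasts that stands in the CA3 list, was at 36.3 ± 7.48 in WSB/EiJ and 13.7 ± 3.0 in C57BL/6J. It is among the CA3 members counted as differing. Cacng5, an AMPA receptor regulator, was at 31.0 ± 5.19 in CAST/EiJ and 12.5 ± 2.75 in C57BL/6J.

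Nnt, the nicotinamide nucleotide transhydrogenase known to carry a deletion in C57BL/6J, has a pair of identifiers in the table and was left out of the list tests. The identifier with more counts was at 15.1 ± 1.91 CPM in C57BL/6J and 19.1 to 31.0 in the other strains, and the other was at 1.58 ± 1.30 in C57BL/6J and 2.73 to 4.61 elsewhere. Within NOD/ShiLtJ, oligodendrocyte markers had 0 members past the edgeR sex test and 5 lower in females adjusted over the list alone, and microglia markers 0 and 3. In CAST/EiJ, blood markers had 0 members past the test and 3 higher in females adjusted over the list alone. In the interaction test, 7 of 18 interferon-stimulated genes and 4 of 15 clock genes passed adjusted over the list alone. The gene Sostdc1 of the CA2 list is also expressed in choroid plexus. In C57BL/6J male 4, the choroid plexus markers lay 1.62 above those of the other 3 males on the log2 scale.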
